A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

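Total RNA from budding yeast (Saccharomyces cerevisiae) was measured on 6 Affymetrix arrays, 3 from cells with wild-type histone H3 and 3 from cells with H3 in which the lysines at positions 4, 36 and 79 were replaced by arginine. Per the labels, cells grew in selective galactose medium, were moved to selective glucose medium for 6 h and were harvested at an optical density of 0.5 to 0.7. About 20 ug of RNA per sample went into biotin-labelled cRNA. The series design describes replicate cultures, and groups and replicate numbers came from the sample titles. Other time points of the design were not analysed here.

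The deposited values are probe set intensities on a linear scale, made with MAS5 per the submitters' processing notes, with the version not given in the sources used here. The table held 9335 probe sets, of which 60 were control probe sets. A script tested the steps in which the values were written. The 3 wild-type arrays had a trimmed mean of 125.1 and steps of 0.1. All values of the 3 mutant arrays were whole multiples (tolerance 0.001 of a step) of smaller steps, which equals a further factor of 0.888, 0.869 and 0.767 for mutant replicates 1, 2 and 3. Dividing by these factors returned a trimmed mean of 125.1. What set the factors is not given in the sources used here.

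Control probe sets were left out and each array was scaled to a 2% trimmed mean of 500, which removes those factors. The deposited intensities without this scaling were an alternative. Probe sets with a mean scaled signal of at least 50 over the 6 arrays were tested, 6808 in all. The test was limma 3.58.1 (lmFit and eBayes with an intensity trend, R 4.3.3) on log2(signal + 16), with Benjamini-Hochberg adjustment over all probe sets tested. Differences are mutant minus wild type on that scale, which understates the change of dim probe sets. A call is an adjusted p under 0.05. The number of arrays limits the precision: the median SE of a difference was 0.16 on the log2 scale. No detection calls were used here.

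Probe sets were named through a platform annotation and a gene table of assembly R64. Exactly 1 gene was listed for 6504 probe sets, which all matched the gene table and covered 5656 genes. Several genes were listed for 328 probe sets and none for 2503, controls included. No gene is named from a probe set with several genes, apart from the targeted H3 genes and the YRF1 family, which are given as families.

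Gene lists, 33 in number, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Each gene entered with its brightest single-gene probe set. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, and lists with fewer than 3 tested members were not tested, which left out the core histone list. One written name, ARG5,6, matched no gene. Another, CRT1, was skipped because the gene table gives it to a different gene than the one meant, which was already listed under RFX1. The fixed plan set telomere-proximal genes by distance where usable positions existed. The files name no genome build, so the planned fallback was used: the last 10 open reading frames on each chromosome arm by systematic name. The plan left open whether this set belongs with the lists in the adjustment, and it was adjusted with them, giving 33 tests.

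The rule for named genes took, among single-gene probe sets with adjusted p under 0.05 and no overlap between the 3 mutant and 3 wild-type values, the 12 largest rises and the 12 largest falls. It added HHT1, HHT2, GAL1, GAL7, GAL10 and GAL80, and up to 4 members with the smallest adjusted p in the direction of each list with a camera adjusted p under 0.05. Genes outside the rule are marked as chosen after their values were seen.

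The procedure was tested on simulated data with 200 changed probe sets among 6808 for this comparison. It recovered 100% of changes of 2 on the log2 scale, 94.0% of changes of 1 and 13.4% of changes of 0.5, with 10 false calls among 148. The simulated noise was normal, independent between probe sets and equally wide in both groups. It therefore left out correlation between probe sets and the wider spread of the mutant arrays. Alternatives were 3 other scalings, offsets of 1 and 64, no filter or a filter at 200, no intensity trend, the replicate number as a block, an estimated correlation for camera, and leaving out each sample in turn with the same probe sets tested.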

Results

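Gene expression was compared between yeast with wild-type histone H3 and yeast whose H3 carried arginine in place of lysine at positions 4, 36 and 79. These lysines are methylated in wild-type cells. The cells had been moved from galactose to glucose for 6 h. Per the series design this represses wild-type H3 and leaves the mutant form as the sole H3, which the arrays do not measure. There were 3 arrays per group, each from a replicate culture. The correlation between arrays on the log2 scale was 0.985 to 0.989 within the wild type, 0.964 to 0.983 within the mutant and 0.961 to 0.981 between groups. The comparison asks which genes differ between cells with and without the replaced lysines. Any other difference between the groups, in strain or plasmid, cannot be told apart from the lysines.

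The targeted genes were examined first. HHT1 and HHT2 both encode H3, and 3 probe sets are annotated to the pair. For 1 of them the scaled signal was 2868 ± 87.2 (SD, n = 3) in the wild type and 955.7 ± 90.5 (SD, n = 3) in the mutant. It fell by 1.57 on the log2 scale (SE 0.12, limma adjusted p = 0.0013), to 33.3% of the wild-type mean. A brighter probe set gave 13765 ± 1118 (SD, n = 3) and 12817 ± 1479 (SD, n = 3), a difference of -0.11 (SE 0.11, limma adjusted p = 0.648). The last lay below the signal filter at 8.88 and 18.6. The labels do not say which sequence each probe set covers, so these values do not show the substitutions. The tested probe sets of the pair disagree. A lower H3 RNA level and replaced bases under the probes could each lower 1 probe set, and these cannot be told apart. GAL1, GAL7 and GAL10 were dim in both groups. GAL7, which encodes a galactose-pathway transferase, gave 85.3 ± 7.96 (SD, n = 3) in the wild type and 100.04 ± 24.6 (SD, n = 3) in the mutant (limma adjusted p = 0.650). GAL10 gave 98.4 ± 16.5 and 118.8 ± 41.8 (adjusted p = 0.677). The signs of the GAL7 and GAL10 differences, 0.17 and 0.20, turned with the deposited scaling, and that of GAL10 also without mutant replicate 1 (-0.026). GAL80, the repressor of the pathway, was brighter, at 567.4 ± 74.3 and 466.5 ± 79.5 (SD, n = 3), and differed by -0.28 (adjusted p = 0.381), and GAL1 lay below the filter with a mean of 33.2.

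The mutant had lower RNA levels of BNA6, BNA1 and TNA1, of the subtelomeric gene COS7 and of the mating-type switching endonuclease HO. BNA6, an enzyme of NAD synthesis from tryptophan, had a scaled signal of 1147 ± 20.7 (SD, n = 3) in the wild type and 354.9 ± 79.0 (SD, n = 3) in the mutant, and fell by 1.67 (SE 0.16, adjusted p = 0.0019). BNA1, of the same pathway, fell by 1.44 (SE 0.14, adjusted p = 0.0019), and TNA1, the nicotinic acid transporter, fell by 1.27 (SE 0.15, adjusted p = 0.0057). HO fell by 1.28 (SE 0.16), from 435.7 ± 5.79 to 172.1 ± 35.4 (SD, n = 3). The largest named fall was that of COS7, which dropped by 1.83 (SE 0.20, adjusted p = 0.0037). HUA1 fell by 1.56, YIL014C-A fell by 1.55, AIF1, a homologue of apoptosis-inducing factor, fell by 1.33, and CDC26, a subunit of the anaphase-promoting complex, fell by 1.29. ADE8, of purine synthesis, fell by 1.17 and YFR018C fell by 1.15. For UTP22, a factor of ribosomal RNA processing, 1 probe set fell by 1.25, while its 4 other probe sets differed by -0.42 to -0.21 and were not called. The UTP22 call was lost without mutant replicate 1 (adjusted p = 0.066), mutant replicate 3 (0.087), wild-type replicate 1 (0.090) or wild-type replicate 3 (0.083).

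Among the rises, PUL3, a membrane transporter gene, went from 33.2 ± 3.83 to 117.3 ± 14.9 (SD, n = 3), a difference of 1.43 (SE 0.16, adjusted p = 0.0041). SAS4, a subunit of a histone acetyltransferase complex, rose by 1.35 (SE 0.18), from 142.7 ± 17.7 to 392.3 ± 87.6 (SD, n = 3). PXA2, part of the peroxisomal fatty acid transporter, rose by 1.35, GPI10, of membrane anchor synthesis, by 1.26 and YNR064C by 1.38. SNO1 and SNZ1, a pair of vitamin B6 synthesis genes, rose by 1.08 and 0.99. MAL11, a maltose transporter, rose by 0.99. HDA3, a subunit of a histone deacetylase complex, rose by 0.98, as did the small nucleolar RNA SNR56, and the vacuolar transporter VMR1 rose by 0.97. A probe set annotated to the 5S ribosomal RNA gene RDN5-1, which has near-identical copies, rose by 1.51 (SE 0.20, adjusted p = 0.0073), and its other probe set by 0.86 (SE 0.14, adjusted p = 0.019). Without mutant replicate 1 the calls of RDN5-1 (adjusted p = 0.059), YNR064C (0.079), PXA2 (0.054), GPI10 (0.102), SNR56 (0.099), HDA3 (0.099) and VMR1 (0.118) were lost. Each of the last 4 was also lost without mutant replicate 3, at an adjusted p of 0.070 to 0.102, and without wild-type replicate 1, at 0.055 to 0.129. MAL11 was lost without wild-type replicate 1 (0.051). Without wild-type replicate 3 the adjusted p of SNR56 was 0.076, that of HDA3 0.129 and that of VMR1 0.136, and without wild-type replicate 2 that of SNR56 was 0.060. With no signal filter these 4 genes had adjusted p of 0.051 to 0.068, as had UTP22 (0.059), and VMR1 had 0.069 on the deposited scale.

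**Figure D1:**
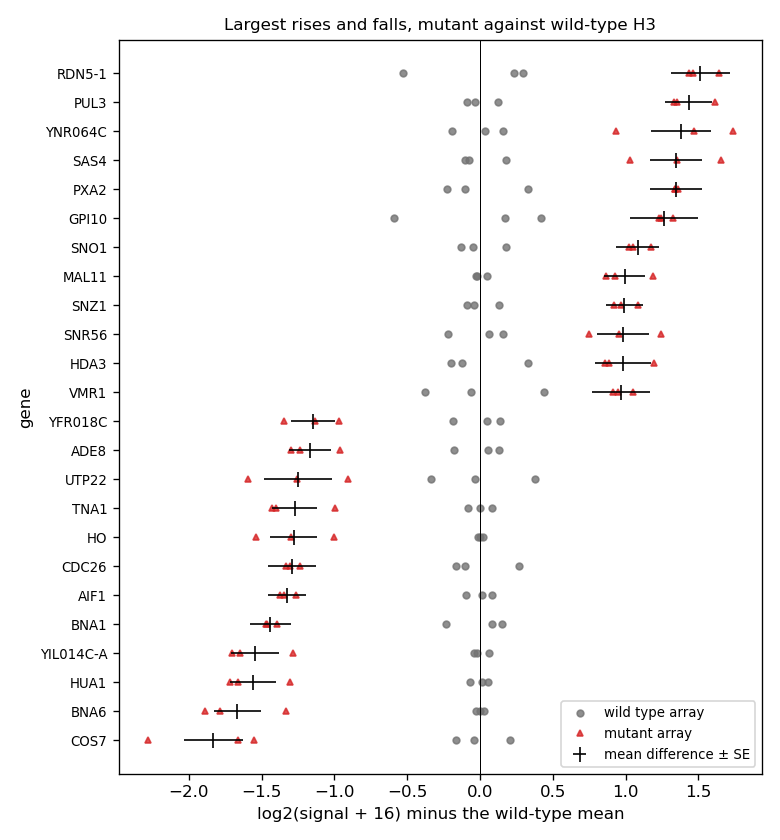
The plot gives, for the 12 largest named rises and 12 largest named falls, each array's log2(signal + 16) minus the wild-type mean (x axis) per gene (y axis). Circles are wild-type arrays, triangles mutant arrays, and black marks the mean difference with its SE. In each gene the 3 mutant arrays lie apart from the 3 wild-type arrays, from COS7 at -1.83 to 1 of the 2 RDN5-1 probe sets at 1.51.

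Over all 6808 probe sets tested with limma, 61 were higher and 92 lower in the mutant at an adjusted p under 0.05. Of these, 13 and 33 changed at least 2-fold. Exactly 1 gene was listed for 110 of the 153, of which 46 were higher and 64 lower. The groups did not overlap in 25.8% of the probe sets tested, where chance gives 10%. The balance of higher and lower calls depended on the scaling, with more lower than higher under each of 4 scalings. With the intensities as deposited, in which the mutant arrays carry a further factor below 1, the median difference of all probe sets was -0.22 in place of 0.02, and 31 probe sets were higher and 372 lower. Each left-out array moved the counts: 16 higher and 23 lower without wild-type replicate 1, 22 and 29 without wild-type replicate 2, and 17 and 39 without wild-type replicate 3. They were 13 and 33 without mutant replicate 1, 124 and 140 without mutant replicate 2, and 24 and 37 without mutant replicate 3. Called genes with a coding length over 3000 bases were mostly higher, 12 against 1 lower, while those of up to 500 bases numbered 1 higher and 6 lower. Over the 5045 genes with a coding length, adjusted over these alone, 14 long genes were higher and 2 lower. With each array's length trend removed, a check chosen after seeing the data, 5 were higher and 2 lower, and the median of long genes went from 0.11 to -0.04. The removal takes out any group difference that follows length, whatever its cause, so it does not say what caused the pattern.

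**Figure D2:**
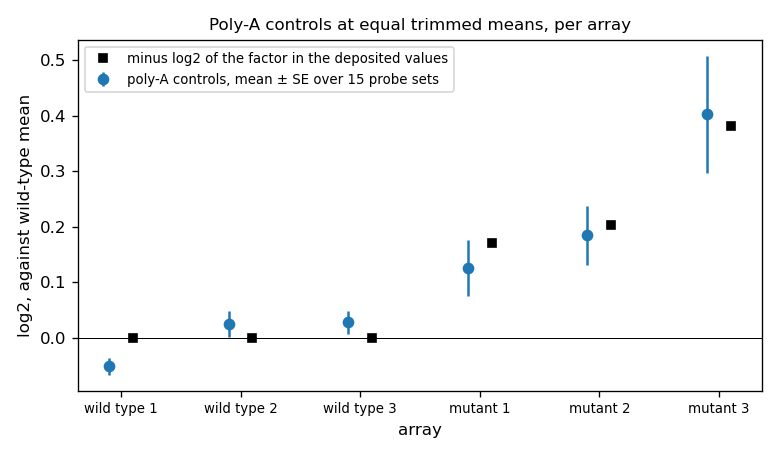
The plot gives, for each of the 6 arrays (x axis), the mean log2 level of 15 poly-A control probe sets against the wild-type mean (y axis, log2) once all arrays have equal trimmed means, with its SE over probe sets, and squares for minus log2 of the further factor in the deposited values. The mutant arrays lie at 0.13, 0.18 and 0.40 for the controls and at 0.17, 0.20 and 0.38 for the factor.

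Of 32 gene lists tested, 5 were higher and 6 lower at a camera adjusted p under 0.05, 11 in all, none with an estimated correlation, and another split of the 6 arrays into 3 and 3 gave up to 9. The COS genes, a subtelomeric family of membrane proteins, showed the lowest camera p. All 6 tested members had lower means in the mutant, and 5 were called lower (6 when adjusted over the list alone). The median difference was -0.95 (camera adjusted p = 1.01e-08), with an adjusted p = 0.097 with an estimated correlation. COS10 fell by 1.04, COS8 fell by 0.99 and COS4 fell by 0.90. Of the other probe sets of COS8, 1 fell by 0.93 and 1 differed by -0.52 with no call. Leaving out an array ended some of these calls. COS10 had an adjusted p = 0.056 and COS4 and COS8 0.072 without mutant replicate 1, and the 3 genes had 0.064 to 0.065 without wild-type replicate 1 and 0.060 to 0.073 without wild-type replicate 2. COS10 had 0.070 without mutant replicate 3 and 0.101 without wild-type replicate 3. Probe sets of this family can share sequence, so its members may not be measured separately.

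The sulphur amino acid genes were higher as a list of 25 (median difference 0.18, camera adjusted p = 0.0076). Called higher were 2 members, and 8 were when adjusted over the list alone. The adjusted p = 0.32 with an estimated correlation. MET1, of sirohaem synthesis for sulphite reduction, rose by 0.91 (SE 0.14, adjusted p = 0.012). SAM3, the S-adenosylmethionine permease, rose by 0.91 at its brightest probe set, while its 4 other probe sets ranged from -0.78 to 0.84 with no call. The list lost its call without probe sets of mean signal under 200 (camera adjusted p = 0.056) and without mutant replicate 1 (0.066). MET1 lost its call without wild-type replicate 1 (adjusted p = 0.059) or wild-type replicate 3 (0.067). The haploid-specific genes were lower as a list of 9 (median -0.24, camera adjusted p = 0.013, adjusted p = 0.36 with an estimated correlation). HO was the only member called over all genes, and 3 were when adjusted over the list alone. FUS3, a mating kinase, differed by -0.52 (adjusted p = 0.089) and at its other probe set by -0.75 (adjusted p = 0.14). The a-specific genes, expressed in cells of mating type a, had a median of -0.23 over 7 genes (camera adjusted p = 0.032, adjusted p = 0.54 with an estimated correlation), with no member called over all genes and 2 lower when adjusted over the list alone. That list lost its call without wild-type replicate 3 (camera adjusted p = 0.067) or mutant replicate 2 (0.107).

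The ergosterol list of 23 genes had a median of -0.12 (camera adjusted p = 0.021, adjusted p = 0.53 with an estimated correlation). At the probe set with which each gene entered, its only called member was ERG26, also when adjusted over the list alone. ERG26, a sterol synthesis enzyme, fell by 0.64 (adjusted p = 0.046). Both calls were fragile: the list was lost without wild-type replicate 1 (camera adjusted p = 0.061) or mutant replicate 1 (0.132), and ERG26 without any of 5 arrays, at an adjusted p of 0.102 (without mutant replicate 3) to 0.179 (without wild-type replicate 3), the others being wild-type replicates 1 and 2 and mutant replicate 1. ERG26 had 0.061 with no signal filter and 0.053 without an intensity trend. For ERG12, the probe set in the list differed by -0.49 (limma adjusted p = 0.108). Another of its probe sets fell by 1.09 and was called (limma adjusted p = 0.0499). Its remaining probe sets differed by -0.69 and 0.14 with no call. No member was called, over all genes or adjusted over the list alone, in the remaining lists with a camera adjusted p under 0.05. Lower were glycolysis and fermentation (17 genes, median -0.14, camera adjusted p = 0.0052, adjusted p = 0.65 with an estimated correlation) and cytosolic ribosomal proteins (75 genes, median -0.06, camera adjusted p = 0.018, adjusted p = 0.70 with an estimated correlation). The ribosomal protein list lost its call with quantile normalization (camera adjusted p = 0.565), without wild-type replicate 3 (0.067) and without mutant replicate 3 (0.333). The glycolysis list lost its call without mutant replicate 3 (0.077). The phosphofructokinase gene PFK1 differed by -0.52 (adjusted p = 0.096). Higher were proteasome (32 genes, median 0.18, camera adjusted p = 0.011), G2/M (29 genes, median 0.26, camera adjusted p = 0.018) and heat shock chaperone genes (24 genes, median 0.18, camera adjusted p = 0.021). Each of these 3 had an adjusted p = 0.53 with an estimated correlation. On the deposited scale the proteasome list gave a camera adjusted p = 0.065 and the heat shock list 0.134. The heat shock list gave 0.052 without wild-type replicate 2. The mitochondrial chaperone gene HSP78 differed by 0.70 (adjusted p = 0.066). The respiration list (48 genes, median 0.10) was at the threshold (camera adjusted p = 0.0497, adjusted p = 0.53 with an estimated correlation) and lost its call under 6 other settings and without any of 4 arrays (0.084 without wild-type replicate 1, 0.131 without wild-type replicate 2, 0.149 without mutant replicate 1, 0.287 without mutant replicate 2). The other 21 lists tested had camera adjusted p from 0.156 to 0.967, the list of H3 lysine methylation genes among them (0.775). In these the cell wall and G1/S lists had medians of 0.01 and 0.04 with means of -0.04 and -0.02, and the glucose-repressed list a median of -0.04 with a mean of 0.0051. On the list of strain and plasmid marker genes, URA3 rose by 0.93 (SE 0.17, limma adjusted p = 0.025), chosen after its value was seen. No other tested marker was called. Such a rise can come from the strains or plasmids, which was not tested.

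Genes near chromosome ends were compared because the replaced lysines are known to bear on silencing there. Among 163 tested genes of the last 10 open reading frames of each arm, 5 were called higher and 10 lower (14 and 21 when adjusted over the list alone). Their median difference was -0.04 against 0.03 for all other genes, with a camera adjusted p = 0.063 (0.023 unadjusted) and an adjusted p = 0.70 with an estimated correlation. Of the 10 lower genes, 5 were COS genes. Without the COS family the camera adjusted p was 0.294. The set was called lower without mutant replicate 2 (camera adjusted p = 0.0068), with no signal filter (0.031) and, chosen after seeing the data, for the last 5 reading frames (0.019), but not for the last 20 (0.346). Of the last 5, the 43 genes left without the COS family had a median of -0.012 (SD 0.44), and their camera adjusted p was also 0.346. BNA6 and AIF1, which fell, and MAL11 and SAM3, which rose, also belong to this set. By distance in reading frames from the end, the share of genes with a lower mean in the mutant was 58.3% for ranks 1 to 5 (48 genes), 55.7% for ranks 6 to 10, 52.6% for ranks 11 to 20, 50.2% for ranks 21 to 40 and 43.4% beyond. These shares keep the COS genes, all with lower means, and only 43 of the 48 genes of ranks 1 to 5 remain without them. The series of shares was not tested.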

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

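The tests in this part were chosen after the values had been seen. The poly-A control probe sets, which read bacterial transcripts meant to be added to the RNA and were left out of the comparison, were higher in the mutant once all arrays had equal trimmed means. Their mean log2 difference was 0.24 over 15 probe sets, with arrays at -0.05, 0.02 and 0.03 in the wild type and 0.13, 0.18 and 0.40 in the mutant. An exact two-sided permutation test of 3 against 3 arrays gave p = 0.1, the smallest such a design allows.

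The mutant arrays carry a further factor below 1, and it follows these controls: on the deposited scale no mutant array's poly-A mean lay more than 0.045 from the wild-type mean, within 2 SD of the wild-type arrays (SD 0.045), while on equal trimmed means all 3 lay beyond 2 SD. The hybridisation controls, added later in the procedure, lay up to 0.396 away on the deposited scale, where the wild-type arrays had an SD of 0.23, and none lay beyond 2 SD on either scale, so these do not decide whether they set the factor. A candidate explanation is that the submitters scaled the mutant arrays to the poly-A controls. Less mRNA per unit of total RNA in the mutant could raise the controls in this way, and so could unequal amounts of added control. Both predict the difference of 0.24, and the labels state no spiking protocol, so these cannot be told apart. If the controls are a true reference, the deposited scale with 31 higher and 372 lower probe sets applies in place of 61 and 92.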

How the results depend on the processing

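The last 5 and last 20 reading frames, the sets without COS genes and the removal of length trends were chosen after seeing the data; the other alternatives were planned. The H3 probe set called lower stayed called and the brighter one uncalled, each with the same direction, in all 15 alternatives. Distances of 10 and 40 kb from chromosome ends were not run, because the files name no build. Where no cause is named, the cause was not tested. Of 30 named probe sets that were called, 252 of 260 results under other settings kept the call and 8 lost it, and 42 of 180 with an array left out lost it (fewer samples). None turned direction. Dim signal limits the rest: raising the filter to 200 left 4265 probe sets.

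As deposited, 31 probe sets were higher and 372 lower (84 at least 2-fold lower), by the factor on the mutant arrays, and 2 lists were shifted up; GAL7 turned to -0.039 and GAL10 to -0.019. With no filter 33 were higher and 54 lower, over more tests. With a filter at 200 there were 57 lower, 6 and 18 at least 2-fold higher and lower, and 3 lists shifted up. Offsets of 1 and 64 gave 22 and 6 probe sets at least 2-fold higher, since the offset scales the log2 difference of dim probe sets.

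With the replicate block 108 were higher, 147 lower and 52 at least 2-fold lower, and the respiration list had a camera adjusted p = 0.061; it changed no other list. The labels do not say what the numbers pair: deviations of same-numbered arrays correlated at 0.13, 0.16 and 0.04, not all above 0.1, and 5 of the 6 arrays correlated best with their own number.

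With an estimated correlation 0 lists were shifted up and 0 down, with a camera adjusted p of 0.097 (COS), 0.651 (glycolysis), 0.321 (sulphur amino acid), 0.357 (haploid-specific), 0.696 (ribosomal protein), 0.539 (a-specific) and 0.528 (proteasome, G2/M, ergosterol, heat shock and respiration). The sulphur list had 0.056 with a filter at 200, the ribosomal protein list 0.565 with quantile normalization, and as deposited the proteasome list had 0.065, heat shock 0.134 and respiration 0.54. Respiration had 0.093 with median scaling, 0.052 with an offset of 64, 0.061 with a filter at 200 and 0.089 without an intensity trend. Telomere-proximal genes had 0.031 with no filter and 0.019 for the last 5 reading frames, which became 0.346 without COS genes.

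Leaving out each array gave 13 to 124 higher and 23 to 140 lower, 7 to 22 and 21 to 43 of them at least 2-fold, 3 to 6 lists shifted up, and a GAL10 difference from -0.026 to 0.43. The camera adjusted p ranged from 1.46e-05 to 0.077 for glycolysis, 0.0021 to 0.066 for sulphur amino acid, 0.00093 to 0.333 for ribosomal protein, 0.0068 to 0.132 for ergosterol, 0.022 to 0.052 for heat shock, 0.015 to 0.107 for a-specific, 0.0035 to 0.287 for respiration and 0.0068 to 0.485 for telomere-proximal genes.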

Other observations

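The tests in this part, the gene lists below and the YRF1 group were all chosen after the values had been seen, except for the tests of the fixed lists and of telomere-proximal genes on which the counts of splits rest.

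Every one of 15 tested genes of NAD synthesis and uptake had a lower mean in the mutant, with a median of -0.38, and 5 were called lower. Besides BNA6, BNA1 and TNA1 these were BNA5, which fell by 0.86, and NPT1, of nicotinic acid salvage, which fell by 0.61 (adjusted p = 0.048). The values of 9 of the 15 had been looked at before the list was written. The other 6 had a median of -0.27, all below 0 and none called. Of the 15, BNA2 (-0.027, SE 0.26), BNA3 (-0.036, SE 0.15), PNC1 (-0.044, SE 0.14) and NMA1 (-0.18, SE 0.19) differed by less than their SE. Of 11 purine synthesis genes, listed after ADE8 had been seen, ADE8 was the only call and 5 had a lower mean. On a list of vitamin B6 genes 5 were tested, and SNO1 and SNZ1, already seen, were the only calls. The other 3 of that list had a median of 0.04, and 1 had a lower mean. The lists were not tested against each other. A probe set annotated to the 25S ribosomal RNA gene RDN25-1 rose by 0.90 (adjusted p = 0.029), while 1 annotated to RDN5-3 (1.22, adjusted p = 0.060) and 5 annotated to RDN37-1 were not called. Medians of the 16 chromosomes lay between -0.09 and 0.10.

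Probe sets whose annotation lists several genes, copies of YRF1 among them, the helicase genes of the Y′ elements at chromosome ends, had lower means in the mutant. Of 16 tested, 13 were called lower and none higher, with a median of -1.57 and a range from -2.36 to -0.13. They share sequence and are not independent measurements. Relative to the median of all probe sets, their median lay between -1.59 and -1.50 in 4 scalings. A fixed difference in copy number between the strains may lower them. It alone would lower the mutant arrays alike, and their medians were -0.96, -1.46 and -1.82, a range of 0.861 against 0.063 in the wild type. Single YRF1 probe sets did not all show this: their log2 SDs were 0.051 to 1.11 in the mutant and 0.11 to 0.67 in the wild type. The probe set brightest in the wild type, which fell by 0.94, had SDs of 0.145 in the mutant and 0.140 in the wild type. The mutant arrays also varied more over all probe sets (r from 0.964 to 0.983 within the mutant and 0.985 to 0.989 within the wild type), and DNA was not analysed here, so copy number stays open. A fall as large as the YRF1 median in all genes near chromosome ends is excluded: the 157 telomere-proximal genes without the COS family had a median of -0.032 (SD 0.42), and 1 of them fell as far as the YRF1 median. A smaller fall of such genes stays open (camera adjusted p = 0.294), and would leave most of the median YRF1 difference unexplained.

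Longer genes tended to be higher in the mutant. Across 5045 genes, which are not independent replicates, Spearman's rho between the difference and coding length was 0.16. Set against the mean of all arrays, the correlation was -0.16, -0.02 and -0.16 in the wild-type arrays and 0.15, -0.03 and 0.19 in the mutant arrays. A rise of long genes in the mutant could give this: the mean correlation was higher by 0.21, with overlapping groups (exact two-sided permutation p = 0.2). A lower yield of long transcripts in the wild-type arrays could give it too, and would raise their 3′ to 5′ ratios; the mean log2 ratio of 3 control genes was 0.13 higher in the mutant, with overlapping groups (exact two-sided permutation p = 0.4). Neither p can go below 0.1 with 3 arrays per group. As the groups overlapped on both measures, the pair cannot be told apart. Among these genes, with the adjustment over them alone, removing each array's length trend left 36 higher and 67 lower genes in place of 55 and 66, with 99 calls shared, and 5 in place of 14 higher genes over 3000 bases. That removal takes out differences that follow length whatever their cause, so it does not tell the pair apart either.

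The 6 arrays make only 10 splits into 3 and 3, too few for a share under 0.05. The real split was the only 1 of the 10 with 153 probe sets called, and the highest other gave 0 with limma. For 2-fold calls, 1 of 10 splits reached 46, and the highest other gave 0. At an unadjusted p under 0.05 the real split gave 1334 probe sets and the others 71 to 373. The other splits mix mutant and wild-type arrays, so a difference between the groups adds to their spread and lowers their counts. They are therefore no plain measure of chance. For gene lists, 1 of 10 splits reached 11 lists called, and the highest other gave 9. For telomere-proximal genes 4 of 10 splits gave a camera p as small, with a highest other -log10 p of 3.25 against 1.64.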
